A study of Mus musculus with 48 samples.

How the data were processed

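Hippocampal RNA from 48 mice of the outbred CD-1 stock was measured by stranded, poly(A)-selected RNA sequencing. Per the labels' protocols, dams drank water with lead (Pb, 100 ppm), manganese (Mn, 2 g/L), both metals, or neither, from 2 weeks before mating until weaning on postnatal day 21, for 8 weeks in all, and offspring of both sexes were sampled at 2 months. Libraries were made with the Illumina Stranded mRNA kit, and paired reads of 100 bases were sequenced on a NovaSeq instrument, per the labels' protocols. The values used here are whole-number read counts per gene in 1 table, as deposited by the authors, with no normalization. Per the submitters' processing notes, the tools used included Trim Galore 0.6.9, STAR 2.7.10b, featureCounts 2.0.6, R 4.4.2, edgeR and limma, with the mouse build GRCm39. How featureCounts was set for strand, multi-mapping reads and overlapping genes is not given in the sources used here, so values of genes with near-identical copies, such as the haemoglobin and ribosomal protein genes, are uncertain where reads could be shared.

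Samples were grouped by the sex and treatment in the labels into 8 groups of 6 animals, and all 48 columns were used. The labels number the animals 1 to 6 in every group and do not state which animals were littermates. Exposure was given to dams, and pups of 1 litter are not independent, so the p-values measure the spread between animals and not between litters. Within groups, the counts of every pair of libraries differed by at least 8.9 times the sampling noise (chi-square per degree of freedom, genes with at least 50 summed counts), so no library was counted as a repeat of another. Of the 57126 gene identifiers, 51884 matched a symbol in the reference names, and these held 99.52% of all counts. Another 131 identifiers whose symbol was shared by several identifiers were kept as identifiers. The reference annotation in use here was GENCODE M21, on another build than the files, so no coordinates are printed and it served only for gene names, transcript lengths and the chromosome of each gene.

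The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM normalization, genes kept by filterByExpr, all 48 libraries in 1 fit with a term per group, and Benjamini-Hochberg adjustment over the 16360 genes tested in each comparison at a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the root of F and are approximate. There were 16 comparisons: each exposure against control within a sex, the combination against each metal, the Pb by Mn interaction within a sex, the sex by exposure interaction, and the sex difference in controls. CPM values use TMM-scaled totals, and log2 CPM has a prior count of 2. Total counts ranged from 6.27 to 27.6 M per library (median 15.1 M). The median SE of a log2 fold change between 2 groups was 0.16. Against a group with no counts of a gene, a bound uses a floor of 3 counts over the group and covers counting error only. In simulated data for male Mn against control, on 16360 genes, the test called 40.3% of genes changed by 1.5-fold, 73.1% of those changed by 2-fold and 93.9% of those changed by 4-fold, with 9 false calls among 147.

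Before the data were examined, the design, the 33 gene lists (pathways, cell types, neighbouring tissues, RNA quality and sex-linked genes), the rule for named genes and the alternatives were fixed. Lists were tested in limma 3.58.1 with camera on log2 CPM at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison, and an estimated correlation and the rotation test fry were run beside it. The smallest-p members of lists are given as values, and Lefty1, near 0 in controls, as CPM. The rule named up to 12 rises and 12 falls per exposure against control among genes past the threshold with a mean log2 CPM of at least 0. Where fewer than 10 passed, it named the 10 genes of smallest p, leaving out unnamed gene models and pseudogenes. It added up to 4 members of smallest p of each called list, of which at most the 2 of smallest p are given here (some members are not reported here), and 9 fixed genes (Slc30a10, Slc39a14, Alad, Mt1, Mt2, Oxtr, Avpr1b, Fos and Bdnf). In other comparisons it named the 6 largest rises and falls that passed. Mean log2 CPM of the cell type, tissue and quality lists per library was compared between exposed and control animals by two-sided exact permutation tests (924 arrangements, 114 tests, smallest possible p 0.0022). A transcript length trend, the slope of a library's centred log2 CPM on log2 transcript length over 10206 genes, was computed as a measure of RNA quality; 98.4% of the genes tested had a length. Correlations of fold changes between exposures share controls, so 10 simulations of unchanged groups and controls split by number (1 to 3 for 1 exposure, 4 to 6 for the other, and the reverse, averaged) were run beside them, between the sexes too.

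Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma voom without and with library weights, a fit on only the groups compared, the animal number as a block, surrogate variables from sva 3.50.0 (7 estimated, 5 used) and a threshold of 0.10. Added after seeing the data were fits without male Pb 6 and female Pb 2, without male control 4, female control 1 and female Pb 4, without female control 5, without male control 5, without female Pb+Mn 1, and without female Mn 1 and female Mn 5, a fit with the length trend, a fit with thalamus and choroid plexus scores, and the block in the list tests. So were a block of same-numbered males and females of an exposure (24 pairs) for comparisons between the sexes, and leaving out each library in turn in the counts of genes, the sex-linked genes and the list tests. Named genes with a library far from its group were fitted without that library, and for switch-like genes exposures were also shuffled over same-numbered pairs (10000 times). States shared by same-numbered males and females of different exposures were set against 10000 renumberings, and the mean log2 CPM of 4 X-linked genes (Eif2s3x, Kdm6a, Kdm5c and Ddx3x) was compared between libraries. Figures were drawn with matplotlib 3.10.9.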

Results

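RNA sequencing counts were available for the hippocampus of 48 CD-1 mice aged 2 months, whose dams had drunk lead, manganese, both metals or plain water from before mating until weaning. Each of the 8 combinations of sex and exposure held 6 animals. Total counts per library averaged 16.3 ± 7.27 M (M, mega) in male controls, 13.7 ± 1.64 M in male Mn, 17.7 ± 5.26 M in male Pb and 18.8 ± 4.3 M in male Pb+Mn (SD, n = 6 each). In females they averaged 14.3 ± 6.17, 16.1 ± 3.83, 16.1 ± 3.19 and 15.5 ± 2.9 M in the same order. The study's title contrasts manganese with concurrent lead for social processing in males, and the comparisons below ask which hippocampal genes differ with each exposure in each sex.

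Sex-linked genes were examined first, as a check of the labels. Xist, the long non-coding RNA that silences an X chromosome, had a median of 104 CPM in the 24 females and 0 CPM in the 24 males. The Y-linked RNA helicase gene Ddx3y ranged from 25 to 40.6 CPM in males and did not exceed 0.0714 CPM in females. Between control groups, 7 genes passed the edgeR threshold: Xist and the X-linked translation initiation gene Eif2s3x rose in females, and Ddx3y, Eif2s3y, Uty, Kdm5d and Gm29650 fell (Gm29650, an unnamed gene model, was named after its values were seen). Eif2s3x differed by 0.47 ± 0.08 on the log2 scale (SE, adjusted p = 0.0023, female control 56.6 ± 6.43 CPM against 40.7 ± 3.48 CPM). Ddx3y, Eif2s3y and Uty had no counts in female controls and were at least 987-fold, 491-fold and 323-fold lower there. Xist averaged 94.5 ± 57.5 CPM in female controls and 4.09 ± 9.97 CPM in male controls (adjusted p = 1e-04). Male control 4 held 24.4 CPM of Xist beside 30.8 CPM of Ddx3y, and female Pb 4 held 0.0684 CPM of Xist. The Xist call was lost with DESeq2 and both limma fits. Fitted on the control libraries alone, 4 genes passed and neither Xist (adjusted p = 1) nor Eif2s3x (adjusted p = 0.46) did. Eif2s3x was also lost without the filter on low counts (adjusted p = 0.084) and with same-numbered males and females as a block (0.058, 5 genes passing), and its adjusted p ran from 1.8e-08 to 0.46 over its alternatives. Leaving out 1 control library at a time, 7 genes passed each time.

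**Figure D1:**
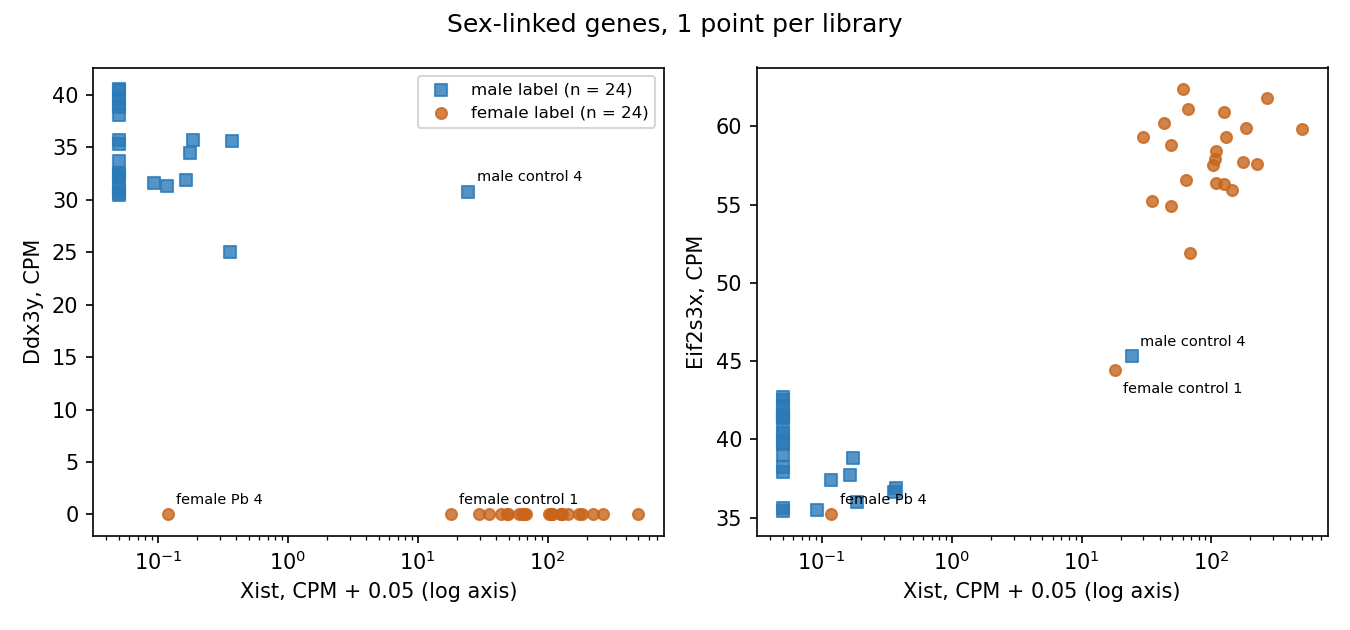
Ddx3y (left) and Eif2s3x (right) in CPM against Xist in CPM + 0.05 on a log axis, 1 point per library, squares for the 24 libraries with a male label and circles for the 24 with a female label. Male control 4 (Xist 24.4 CPM), female control 1 (Eif2s3x 44.4 CPM) and female Pb 4 (Xist 0.0684 CPM) lie apart from the other libraries of their sex.

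To determine which genes differ in males after developmental manganese, 6 exposed males were compared with 6 control males. No gene passed the threshold. The genes of smallest p included the zinc finger gene Zfp112 (log2 fold change 0.41 ± 0.11, 6.18 ± 0.37 against 4.56 ± 0.609 CPM), the G protein subunit gene Gng4 (0.50 ± 0.14) and the exoribonuclease gene Dis3 (0.34 ± 0.10). Lower values were seen for the connexin gene Gjc1 (-0.79 ± 0.24), the glycosyltransferase gene Galnt14 (-0.43 ± 0.14) and Rsph3b (-0.99 ± 0.33), each below the control mean in 6 of 6 exposed males. Elmod3 had -0.34 ± 0.11, while Myo18b (0.63 ± 0.19) and Cpeb1os1 (0.61 ± 0.19) were above it in 6 of 6. None of these met the adjusted threshold (edgeR, adjusted p = 1 each). Xist was also in this set, with 24.4 CPM in male control 4 and at most 0.115 CPM in the other male controls, and it was the 1 list member that passed when adjusted over the list alone, with 0 over all genes. Markers of CA1 pyramidal neurons ranked higher than other genes (9 of 10 members positive, median 0.45, camera adjusted p = 1e-06, estimated-correlation adjusted p = 0.21), among them the mannosidase gene Man1a (0.49 ± 0.22) and Lefty1, a signalling antagonist gene near 0 in controls (3 against 0.0241 CPM). Interneuron markers also ranked higher (13 of 15, median 0.15, adjusted p = 0.0013, estimated-correlation adjusted p = 0.39), with somatostatin (Sst, 0.47 ± 0.23) and the transcription factor gene Dlx2 (0.32 ± 0.21), as did mitochondrially encoded genes (12 of 13, median 0.21, adjusted p = 0.00037, estimated-correlation adjusted p = 0.77, mt-Nd3 1.13 ± 0.51 and mt-Atp8 0.66 ± 0.48). These 2 genes had few counts (0.587 against 0.233 CPM and 0.923 against 0.584 CPM). Dentate granule cell markers ranked lower (1 of 12 positive, median -0.20, adjusted p = 0.0067, estimated-correlation adjusted p = 0.77, Stxbp6 -0.33 ± 0.18 and Dsp -0.39 ± 0.26). So did markers of thalamus and habenula (0 of 14, median -0.79, adjusted p = 3.6e-05, estimated-correlation adjusted p = 0.77, Prkcd -1.18 ± 0.57 and Ptpn3 -0.39 ± 0.19) and of meninges (0 of 14, median -0.47, adjusted p = 0.00015, estimated-correlation adjusted p = 0.77, Col1a2 -0.64 ± 0.31 and Col1a1 -0.58 ± 0.30), both tissues that border the hippocampus. The estimated-correlation adjusted p, given beside that at the preset correlation, passed for no list in any exposure comparison, and the rotation test fry called 0 lists in any exposure comparison. Male control 5 held 357 CPM of Prkcd and 177 CPM of Ptpn3, against 29.2 to 147 and 86.1 to 109 CPM in the other male controls, and without it Prkcd was at -0.56, Ptpn3 at -0.21, Gjc1 at -0.43 and the CA1 median at 0.30 (adjusted p = 0.0025, 5.7e-08 to 0.88 over its alternatives). The mitochondrially encoded call was lost without Mn 2 (adjusted p = 0.12, median 0.11), with 1.8e-05 to 0.94 over its alternatives. The dentate granule call was lost without control 2 (adjusted p = 0.087), control 6 (0.31), Mn 1 (0.055) or Mn 2 (0.059), with 1.3e-05 to 0.94 over its alternatives. The meninges call was lost without control 3 (adjusted p = 0.079, median -0.19) or Mn 3 (0.13, median -0.28), with 5.3e-07 to 0.94 over its alternatives. The thalamus call was lost without control 5 (adjusted p = 0.054, median -0.41), with 2.5e-09 to 0.99 over its alternatives. The interneuron median moved to 0.07 without Mn 5 with the call kept. The thalamus median moved to -1.35 without Mn 2 with the call kept. At an unadjusted p under 0.05 there were 368 genes, against 818 expected by chance (583 without control 1 and 586 without Mn 2), and DESeq2 and limma voom also called 0.

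To determine which genes differ in males after lead, 6 exposed males were compared with 6 control males, and no gene passed the threshold (smallest adjusted p = 0.34). The genes of smallest p included the complex I assembly gene Ndufaf8 (0.65 ± 0.16, 18.3 ± 5.37 against 11.6 ± 1.73 CPM), the sialyltransferase gene St3gal4 (0.91 ± 0.23), Fgfrl1 (0.50 ± 0.13), the galectin gene Lgals1 (0.55 ± 0.15) and the mitochondrial transfer RNA gene mt-Tp (0.84 ± 0.23). Those with lower values were the chromosomal passenger gene Cdca8 (-0.97 ± 0.23), the interleukin receptor gene Il1r1 (-0.61 ± 0.15, 11.7 ± 2 against 17.8 ± 2.78 CPM), Aatf (-0.41 ± 0.11), the leucine-rich repeat gene Lrrn1 (-0.44 ± 0.12) and the aminopeptidase gene Anpep (-0.60 ± 0.16). Except for mt-Tp, higher in 5 of 6, each lay on 1 side of the control mean in 6 of 6 exposed males. All 30 cytosolic ribosomal protein genes had positive fold changes (median 0.60, camera adjusted p = 3.4e-19, estimated-correlation adjusted p = 0.5), such as Rps20 (0.61 ± 0.19) and Rpl38 (0.74 ± 0.23). Of these, 29 passed when adjusted over the list alone. Nuclear-encoded respiratory chain genes followed (22 of 25, median 0.34, adjusted p = 2.7e-06, estimated-correlation adjusted p = 0.63, 11 adjusted over the list alone, Ndufb8 0.86 ± 0.27 and Cox6c 0.80 ± 0.25). Mitochondrially encoded genes ranked higher too (13 of 13, median 0.51, adjusted p = 1.4e-08, estimated-correlation adjusted p = 0.5, 12 adjusted over the list alone, mt-Nd5 0.49 ± 0.17 and mt-Nd4l 0.92 ± 0.34, the latter at 0.974 against 0.512 CPM). Over all genes tested, 0 members of these lists passed. Dentate granule cell markers ranked lower (1 of 12 positive, median -0.41, adjusted p = 9.5e-05, estimated-correlation adjusted p = 0.5), including Prox1, the transcription factor of granule cell identity (-0.58 ± 0.21), and Dsp (-0.72 ± 0.26). Lists ranking lower also included glucocorticoid-responsive genes (median -0.28, adjusted p = 0.0031, estimated-correlation adjusted p = 0.63, Errfi1 -0.41 ± 0.14 and Zbtb16 -0.31 ± 0.15) and immediate early genes (median -0.23, adjusted p = 0.018, estimated-correlation adjusted p = 0.63, Jun -0.34 ± 0.15 and Bdnf -0.35 ± 0.22). Further such lists were glutamate receptors (median -0.18, adjusted p = 0.018, estimated-correlation adjusted p = 0.63, Grm2 -0.69 ± 0.24 and Grik1 -0.46 ± 0.21) and meninges (median -0.50, adjusted p = 0.04, estimated-correlation adjusted p = 0.63, Fmod -1.01 ± 0.35 and Slc22a6 -0.84 ± 0.31). Choroid plexus markers (18 of 18, median 0.52, adjusted p = 0.00041, estimated-correlation adjusted p = 0.63, Calml4 0.95 ± 0.63 and Foxj1 0.34 ± 0.31) and blood genes (7 of 7, median 0.83, adjusted p = 0.0031, estimated-correlation adjusted p = 0.63, Hbb-bt 1.38 ± 0.44 and S100a9 2.41 ± 0.64) ranked higher, with 3 blood genes past the threshold when adjusted over the list alone. Male Pb 6 held 9.16 CPM of S100a9, 761 CPM of Cox6c and 408 CPM of Rps20. Without it the log2 fold changes were 0.27 for S100a9, 0.44 for Ndufb8, 0.38 for Cox6c, 0.38 for Rps20 and 0.49 for Rpl38. The immediate early call was lost without control 1 (adjusted p = 0.067, median -0.14), control 3 (0.11) or Pb 2 (0.088), with 0.00034 to 0.63 over its alternatives. The glutamate receptor call was lost without Pb 6 (adjusted p = 0.075), with 0.01 to 0.65 over its alternatives. The meninges call was lost without control 3 (adjusted p = 0.3, median -0.26), control 4 (0.21), control 5 (0.052), Pb 1 (0.23) or Pb 6 (0.19), with 0.002 to 0.63 over its alternatives. The respiratory chain median moved to 0.12 without Pb 6 with the call kept. The ribosomal median moved to 0.35 without Pb 6 with the call kept. The glucocorticoid median moved to -0.18 without control 1 with the call kept. The choroid plexus median moved to 0.30 without control 1, 1.83 without control 3, 0.32 without control 5 and -0.25 without Pb 2 with the call kept, where camera still ranked the list higher (adjusted p = 0.039, 3e-09 to 0.92 over its alternatives). The transcript length trend averaged -0.107 ± 0.163 in male Pb and 0.001 ± 0.079 in male controls (SD, n = 6 each), with male Pb 6 at -0.407 and 9.1 for its ribosomal score. At an unadjusted p under 0.05 there were 2046 genes (1354 higher, 692 lower), and DESeq2 and limma voom called 0. As many were found in 13 of 100 splits of these libraries, the real groups counted (median of the others 1128). Without male Pb 6 the unadjusted count was 816 (400 higher, 416 lower), and without it and female Pb 2 it was 1145. Without male Pb 2 the ribosomal pseudogene Rpl14-ps1 passed (adjusted p = 0.024, named after its values were seen). With the length trend as covariate the count was 1050, and the immediate early (adjusted p = 0.1), glutamate receptor (0.65), meninges (0.071) and blood (0.071) calls were lost.

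**Figure D2:**
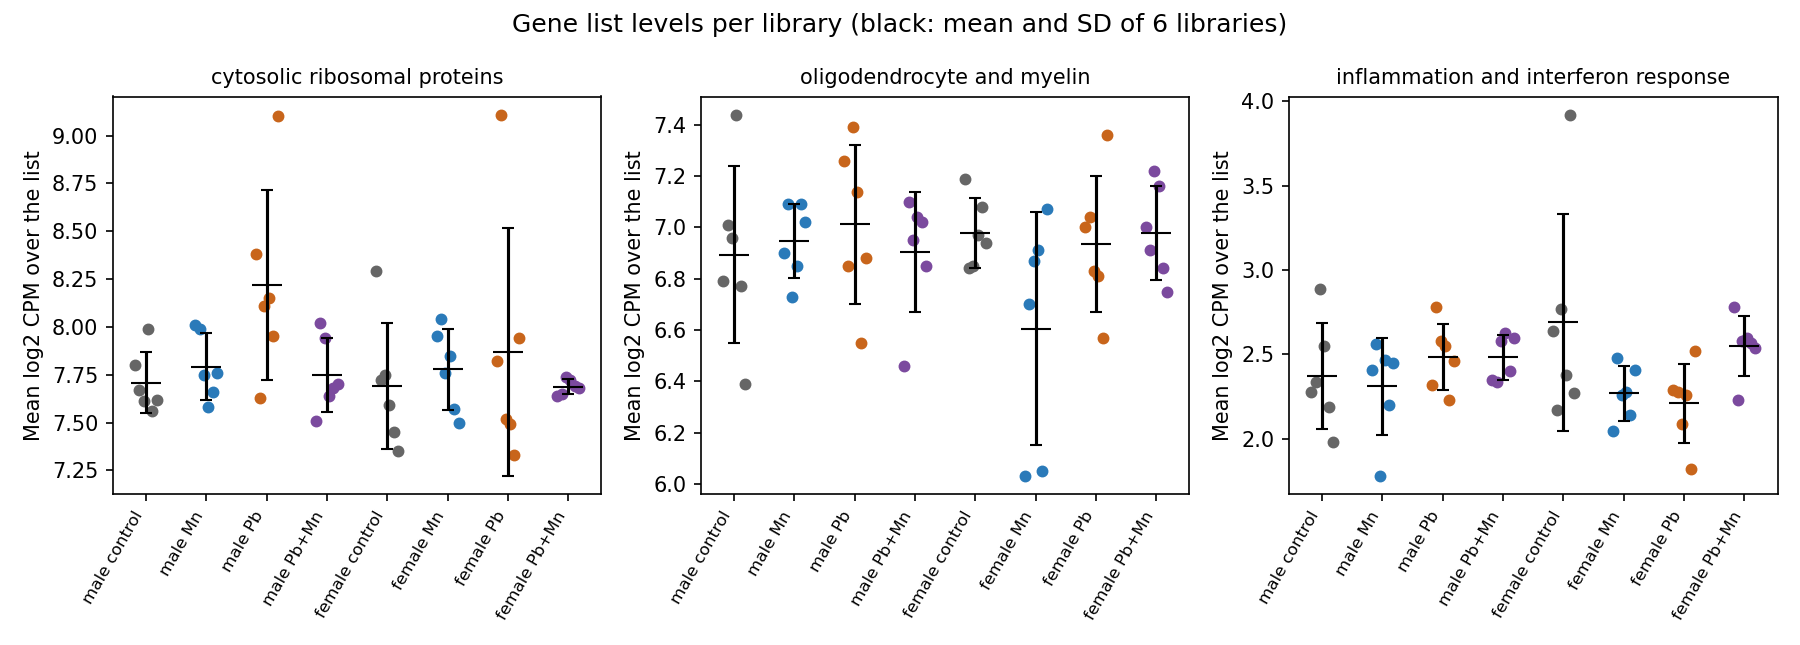
Mean log2 CPM of 3 gene lists per library (vertical axes) in the 8 groups (horizontal axes), 1 point per library, with the mean and SD of 6 libraries in black. Ribosomal protein genes reach 9.1 in 1 male Pb and 9.11 in 1 female Pb library, the myelin genes of female Mn span 6.03 to 7.07, and 1 female control library reaches 3.92 for interferon response genes.

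To determine which genes differ in males after both metals, 6 Pb+Mn males were compared with 6 controls, and no gene passed. Alas2, the enzyme of heme synthesis in red cell precursors, was at 8.62 ± 4.89 against 3.56 ± 1.11 CPM (log2 fold change 1.34 ± 0.35), higher than the control mean in 6 of 6 animals. Ssh1, a cofilin phosphatase gene, had 0.43 ± 0.11 and Arid3a 0.40 ± 0.13. Lower values were those of Cthrc1 (-1.58 ± 0.48), Slc12a8 (-1.18 ± 0.37), the synaptic organizer gene Cbln2 (-0.99 ± 0.30), Mterf1a (-0.81 ± 0.25), Rttn (-0.61 ± 0.18) and the connexin gene Gja4 (-0.60 ± 0.19). Xist was again among the genes of smallest p, with male control 4 as above. Blood genes ranked higher (5 of 7 positive, median 1.12, camera adjusted p = 6e-04, estimated-correlation adjusted p = 0.92), with 4 past the threshold when adjusted over the list alone and 0 over all genes, among them Alas2 and Hbb-bt (1.32 ± 0.44). Immediate early genes, which follow neuronal activity, ranked higher (19 of 22, median 0.22, adjusted p = 0.00028, estimated-correlation adjusted p = 0.92), such as Egr2 (0.88 ± 0.35) and Egr4 (0.51 ± 0.24). Choroid plexus markers (15 of 18, median 0.45, adjusted p = 4.3e-06, estimated-correlation adjusted p = 0.92, Foxj1 0.42 ± 0.31 and Kl 0.79 ± 0.59) and CA1 markers (9 of 10, median 0.24, adjusted p = 0.011, estimated-correlation adjusted p = 0.92, Fibcd1 0.51 ± 0.27) also ranked higher. Respiratory chain genes ranked lower (0 of 25 positive, median -0.12, adjusted p = 6e-04, estimated-correlation adjusted p = 0.92, Uqcrfs1 -0.18 ± 0.09). Without male control 5, which held 3.1 CPM of Slc12a8 against 0.65 to 1.49 CPM in the other male controls, Slc12a8 was at -0.67 and Cbln2 at -0.78. The respiratory chain call was lost without control 1 (adjusted p = 0.058, median -0.06), with 3e-05 to 0.93 over its alternatives. The CA1 call was lost without control 5 (adjusted p = 0.47, median 0.10), Pb+Mn 1 (0.064), Pb+Mn 2 (0.052) or Pb+Mn 5 (0.12), with 0.00038 to 0.93 over its alternatives. The immediate early median moved to 0.14 without control 5 with the call kept. The CA1 median moved to 0.39 without control 2 with the call kept. The choroid plexus median moved to 0.27 without control 1, 1.65 without control 3, 0.22 without control 5, 0.17 without Pb+Mn 1 and 0.11 without Pb+Mn 4 with the call kept. With the length trend as covariate the respiratory chain (adjusted p = 0.19) and CA1 (0.064) calls were lost. There were 480 genes at an unadjusted p under 0.05 in edgeR (222 without control 5), and DESeq2 and limma voom called 0.

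Adding manganese to lead was examined by comparing Pb+Mn with each metal and by the Pb by Mn interaction. In males, Pb+Mn against Pb gave 0 genes past the threshold in edgeR (smallest adjusted p = 0.069) with 3895 at an unadjusted p under 0.05, of which 1441 were higher and 2454 lower in Pb+Mn. Without male Pb 2, 1376 genes passed and without male Pb 5 1483, while without male Pb 6 none did and 1369 were left at an unadjusted p. With the transcript length trend as covariate, 1096 were left at an unadjusted p. That trend averaged -0.107 ± 0.163 in male Pb and 0.047 ± 0.047 in male Pb+Mn (SD, n = 6 each). The count also depended on the tool: DESeq2 called 202 (35 higher, 167 lower), limma voom 0, limma voom with library weights 471 (166 higher, 305 lower), and a threshold of 0.10 in edgeR 893 (184 higher, 709 lower). Pb+Mn against Mn gave 0 and 660 unadjusted in males (408 without male Mn 6, 421 without male Pb+Mn 1) and 0 and 417 in females. Pb+Mn against Pb in females gave 0 and 627 (974 without female Pb 3, 1000 without female Pb 5, 409 without female Pb+Mn 1). The interaction gave 0 genes in males (2249 unadjusted, 916 without male Pb 6) and 0 in females (505 unadjusted, 825 without female control 1, 327 without female control 5). For the male count, 5 of 100 splits of the libraries gave as many, the real groups counted. In all of these except male Pb+Mn against Pb, DESeq2 and limma voom also called 0.

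**Figure D3:**
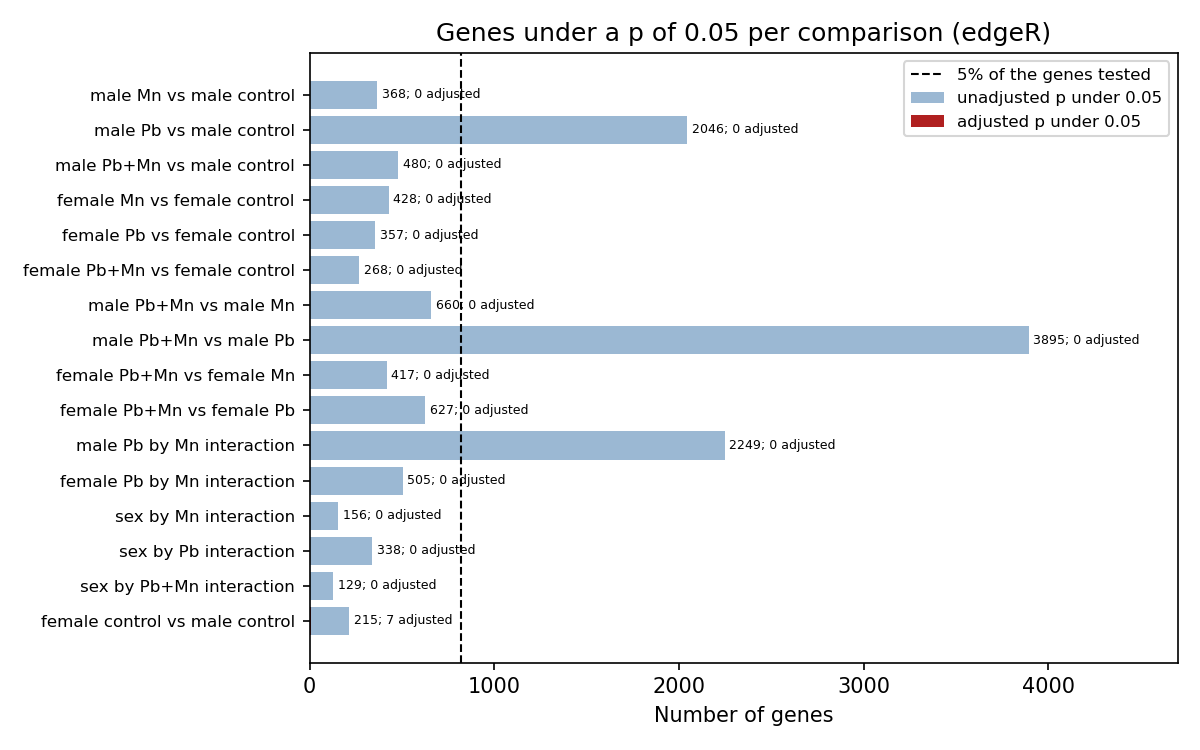
Number of genes (horizontal axis) at an unadjusted p under 0.05 (blue bars) and an adjusted p under 0.05 (red, too few to see, with both counts printed beside each bar) in the 16 comparisons (vertical axis), with 818 genes expected by chance as a dashed line. Only male Pb (2046), male Pb+Mn against Pb (3895) and the male interaction (2249) exceed that line. As many genes were found in 13, 5 and 5 of 100 splits of the libraries, in the same order, the real groups counted. Exceeding the line therefore does not exclude chance.

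To determine which genes differ in females after manganese, 6 exposed females were compared with 6 controls, and no gene passed. All 16 myelin and oligodendrocyte genes had negative fold changes (median -0.34, camera adjusted p = 1.4e-15, estimated-correlation adjusted p = 0.11), such as Cldn11, a tight junction gene of myelin (-0.45 ± 0.15), and Myrf, a regulator of myelin genes (-0.42 ± 0.16), with 0 past the threshold when adjusted over the list alone. The precursor markers Olig2 (-0.28 ± 0.15) and Olig1 (-0.19 ± 0.11) belonged to a list that also ranked lower (1 of 12 positive, median -0.16, adjusted p = 9e-04, estimated-correlation adjusted p = 0.22). The myelin score averaged 6.61 ± 0.45 in female Mn and 6.98 ± 0.14 in female controls (SD, n = 6 each), with female Mn 1 at 6.03, Mn 5 at 6.05 and the other 4 from 6.7 to 7.07. Their dentate granule scores were 5.93 and 5.85, against 5.12 to 5.54 in the other 4. Leaving out any 1 library kept the myelin call, but without both of these the median was -0.10 (5 of 16 positive, adjusted p = 0.025, 1.8e-21 to 0.37 over its alternatives), Cldn11 -0.23 and Myrf -0.26. Interferon response genes ranked lower (1 of 16 positive, median -0.49, adjusted p = 1.3e-07, estimated-correlation adjusted p = 0.11), with Irf7 (-1.61 ± 0.47) and Ifitm3 (-0.76 ± 0.26) passing when adjusted over the list alone and 0 over all genes. Female control 5 held the highest interferon score (3.92) and 17.4 CPM of Irf7, against 0.921 to 3.84 CPM in the other female controls. Without that library the log2 fold change was -0.55 for Irf7 and -0.26 for Ifitm3. The list's adjusted p was then 0.043 (8.7e-10 to 0.37 over its alternatives) and its median -0.08. Other lists ranking lower were thalamus and habenula (median -0.73, adjusted p = 0.0055, estimated-correlation adjusted p = 0.68, Tac2 -1.40 ± 0.62 and Nwd2 -0.65 ± 0.29, and -0.57 and -0.12 without female control 5) and meninges (median -0.44, adjusted p = 0.022, estimated-correlation adjusted p = 0.68, Col1a1 -0.53 ± 0.29 and Slc22a6 -0.57 ± 0.32). So did blood genes (median -0.50, adjusted p = 0.0071, estimated-correlation adjusted p = 0.52, Alas2 -0.70 ± 0.42 and Hba-a1 -0.56 ± 0.45, the latter 0.08 without female control 1, which held 158 CPM against 23.3 to 50.4 in the other controls) and glucocorticoid-responsive genes (median -0.16, adjusted p = 0.0031, estimated-correlation adjusted p = 0.52, Cdkn1a -1.14 ± 0.37 and Pdk4 -0.55 ± 0.23). Ranking higher were CA1 markers (median 0.25, adjusted p = 0.0031, estimated-correlation adjusted p = 0.52, Mpped1 0.28 ± 0.19) and mitochondrially encoded genes (median 0.18, adjusted p = 7.2e-05, estimated-correlation adjusted p = 0.52, mt-Nd5 0.26 ± 0.17, or 0.13 without Mn 5, and mt-Co2 0.23 ± 0.20). The same held for microglia (median 0.12, adjusted p = 0.021, estimated-correlation adjusted p = 0.68, Cx3cr1 0.27 ± 0.12 and Siglech 0.28 ± 0.13) and clock genes (14 of 18 positive, median 0.12, adjusted p = 0.03, estimated-correlation adjusted p = 0.52, Dbp 0.55 ± 0.28 but Nfil3 -0.43 ± 0.22, or -0.24 without control 1). The mitochondrially encoded call was lost without control 5 (adjusted p = 0.16, median 0.06), with 1.5e-11 to 0.73 over its alternatives. The glucocorticoid call was lost without control 3 (adjusted p = 0.29, median -0.09), Mn 2 (0.19, median -0.09) or Mn 4 (0.055), with 1.1e-06 to 0.73 over its alternatives. The clock call was lost without control 1 (adjusted p = 0.26), control 2 (0.091), control 4 (0.079), Mn 1 (0.18), Mn 3 (0.05) or Mn 5 (0.12), with 0.0028 to 0.73 over its alternatives. The CA1 call was lost without control 5 (adjusted p = 0.16, median 0.14), with 0.00027 to 0.73 over its alternatives. The precursor call was lost without control 1 (adjusted p = 0.069, median -0.09), with 0.00012 to 0.57 over its alternatives. The microglia call was lost without control 2 (adjusted p = 0.23), control 3 (0.052), control 5 (0.24), control 6 (0.26, median 0.06), Mn 1 (0.4, median 0.02) or Mn 4 (0.11, median 0.07), with 2.4e-07 to 0.81 over its alternatives. The meninges call was lost without control 4 (adjusted p = 0.087), control 5 (0.43, median -0.29), control 6 (0.22) or Mn 3 (0.57, median -0.29), with 2.2e-05 to 0.81 over its alternatives. The thalamus call was lost without control 5 (adjusted p = 0.53, median -0.32), control 6 (0.12), Mn 1 (0.08) or Mn 3 (0.067), with 0.00017 to 0.81 over its alternatives. The blood call was lost without control 1 (adjusted p = 0.32, median -0.01) or Mn 5 (0.093, median -0.32), with 0.00067 to 0.73 over its alternatives. The mitochondrially encoded median moved to 0.35 without control 1, 0.09 without control 4, 0.08 without control 6 and 0.08 without Mn 5 with the call kept. The glucocorticoid median moved to -0.29 without Mn 1 with the call kept. The interferon median moved to -0.08 without control 5 with the call kept. The CA1 median moved to 0.38 without control 3 with the call kept. The microglia median moved to 0.24 without control 1 and 0.07 without control 4 with the call kept. The thalamus median moved to -1.14 without Mn 4 with the call kept. The blood median moved to -0.79 without Mn 1 with the call kept. Among the genes of smallest p were the fatty acid elongase gene Elovl2 (0.31 ± 0.09), Fbxo30 (0.43 ± 0.13), Pard3b (0.43 ± 0.14) and the semaphorin receptor gene Plxnd1 (0.51 ± 0.16). Lower values were those of Sntg2 (-0.95 ± 0.27), Rhou (-0.45 ± 0.14), Galnt6 (-0.61 ± 0.19), the interferon-induced gene Rtp4 (-1.24 ± 0.37, and -0.60 without female control 5) and Pcdhgb8 (-3.54 ± 1.15, 0.378 ± 0.143 against 4.54 ± 4.52 CPM). There were 428 genes at an unadjusted p under 0.05 in edgeR (smallest adjusted p = 0.91), and DESeq2 and limma voom called 0.

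In females after lead, compared with the same controls, no gene passed. Interferon response genes ranked lower (0 of 16 positive, median -0.51, camera adjusted p = 5.5e-10, estimated-correlation adjusted p = 0.06), with 5 past the threshold when adjusted over the list alone and 0 over all genes. Ifit3, an antiviral effector gene, was at 1.67 ± 0.874 against 6.4 ± 5.59 CPM (-1.85 ± 0.57), Irf7 had -1.50 ± 0.47, and the sensors of viral RNA Ifih1 and Eif2ak2, which are not on the list, had -0.82 ± 0.24 and -0.50 ± 0.14. Without female control 5 these were -1.33 for Ifit3, -0.43 for Irf7, -0.54 for Ifih1 and -0.35 for Eif2ak2. The list's adjusted p was then 0.0034 (5e-13 to 0.24 over its alternatives) and its median -0.16. CA1 markers ranked higher (9 of 10, median 0.40, adjusted p = 1.6e-05, estimated-correlation adjusted p = 0.27), and thalamus and habenula lower (0 of 14, median -0.81, adjusted p = 0.0028, estimated-correlation adjusted p = 0.78, Prkcd -1.04 ± 0.57 and Tcf7l2 -1.27 ± 0.72). Ribosomal protein genes ranked higher (30 of 30, median 0.31, adjusted p = 1.3e-05, estimated-correlation adjusted p = 0.78, Rps27 0.54 ± 0.28 and Rps14 0.49 ± 0.26). Without female Pb 2 Rps27 was at -0.07 and Rps14 at 0. That library had a transcript length trend of -0.362, against -0.068 to 0.159 in the other 5, and the highest ribosomal score (9.11). The ribosomal call was lost without Pb 2 (adjusted p = 0.16, median -0.08), with 5.5e-16 to 0.98 over its alternatives. The thalamus call was lost without control 5 (adjusted p = 0.62, median -0.30), control 6 (0.057), Pb 2 (0.15) or Pb 5 (0.058), with 9.6e-06 to 0.98 over its alternatives. The interferon median moved to -0.16 without control 5 with the call kept. The CA1 median moved to 0.22 without Pb 5 with the call kept. The thalamus median moved to -1.33 without Pb 6 with the call kept. Other genes of smallest p were the adhesion receptor gene Cd44 (-0.74 ± 0.20), the coagulation inhibitor gene Tfpi (-0.64 ± 0.19), Tmem204 (-0.40 ± 0.11), Rad17 (-0.32 ± 0.10), Anapc7 (-0.34 ± 0.11) and the vesicle gene Rab3b (0.68 ± 0.19). There were 357 genes at an unadjusted p under 0.05 in edgeR (680 without control 1, 563 without Pb 2), and DESeq2 and limma voom called 0.

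In females after both metals no gene passed. Cwc22, a splicing factor gene, was at 17.6 ± 9.26 against 71.5 ± 29.6 CPM (-2.04 ± 0.55), below the control mean in 6 of 6 animals. The endothelin gene Edn1 had -1.02 ± 0.28, Efhc2 -0.75 ± 0.23 and Trappc5 -0.23 ± 0.08. The genes with positive values were the glucose transporter gene Slc2a10 (0.81 ± 0.24), the matrix genes Col6a3 (0.74 ± 0.24) and Lama5 (0.55 ± 0.18), and Gli3 (0.41 ± 0.13). Glucocorticoid-responsive genes ranked lower (2 of 16 positive, median -0.27, camera adjusted p = 3.6e-05, estimated-correlation adjusted p = 0.93), and the lipid droplet gene Plin4 (-1.37 ± 0.42) and the sulfotransferase gene Sult1a1 (-0.71 ± 0.22) passed when adjusted over the list alone, with 0 over all genes. Genes of the unfolded protein response (median -0.13, adjusted p = 0.033, estimated-correlation adjusted p = 0.95, Herpud1 -0.22 ± 0.12 and Manf -0.30 ± 0.21, the latter -0.10 without control 1) and of the respiratory chain (median -0.07, adjusted p = 0.043, estimated-correlation adjusted p = 0.95, Ndufb3 -0.20 ± 0.20 and Ndufa1 -0.21 ± 0.22) ranked lower. Choroid plexus markers ranked higher (16 of 18, median 0.90, adjusted p = 0.033, estimated-correlation adjusted p = 0.95, Tmem72 1.78 ± 1.05 and Sostdc1 0.97 ± 0.69). Female Pb+Mn 1 held 82.6 CPM of Tmem72 and 25.9 CPM of Sostdc1, against 0.852 to 15.5 and 2.19 to 9.71 CPM in the other 5, and without it they were at 0.46 and 0.43. The respiratory chain call was lost without control 1 (adjusted p = 0.92, median 0.01), control 4 (0.17), Pb+Mn 1 (0.17), Pb+Mn 2 (0.073), Pb+Mn 3 (0.12), Pb+Mn 4 (0.16) or Pb+Mn 6 (0.065), with 0.0021 to 0.99 over its alternatives. The glucocorticoid call was lost without control 3 (adjusted p = 0.11), with 5.5e-07 to 0.99 over its alternatives. The unfolded protein call was lost without control 1 (adjusted p = 0.71, median -0.03), Pb+Mn 1 (0.12), Pb+Mn 2 (0.14, median -0.08) or Pb+Mn 5 (0.21, median -0.06), with 0.00051 to 0.99 over its alternatives. The choroid plexus call was lost without control 1 (adjusted p = 0.062), control 3 (0.15), control 4 (0.23), Pb+Mn 1 (0.53, median 0.12), Pb+Mn 3 (0.12) or Pb+Mn 6 (0.05), with 0.00015 to 0.99 over its alternatives. The respiratory chain median moved to -0.13 without control 5, -0.12 without control 6 and -0.11 without Pb+Mn 5 with the call kept. The unfolded protein median moved to -0.20 without control 3 with the call kept. The choroid plexus median moved to 1.53 without control 5 with the call kept. There were 268 genes at an unadjusted p under 0.05 in edgeR, and DESeq2 and limma voom called 0.

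Over the 6 exposed groups, 16 of the 40 list calls were kept whichever 1 library was left out. For 6 of these the median also stayed within 1.5 times: CA1 in male Mn, mitochondrially encoded, dentate granule and blood genes in male Pb, blood in male Pb+Mn and myelin in female Mn. Leaving out 1 library cannot show an effect carried by several. The myelin median came nearer to none when female Mn 1 and female Mn 5 (scores 6.03 and 6.05) were left out together, as given above. With an estimated correlation 0 of the 40 passed (smallest adjusted p = 0.06).

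**Figure D4:**
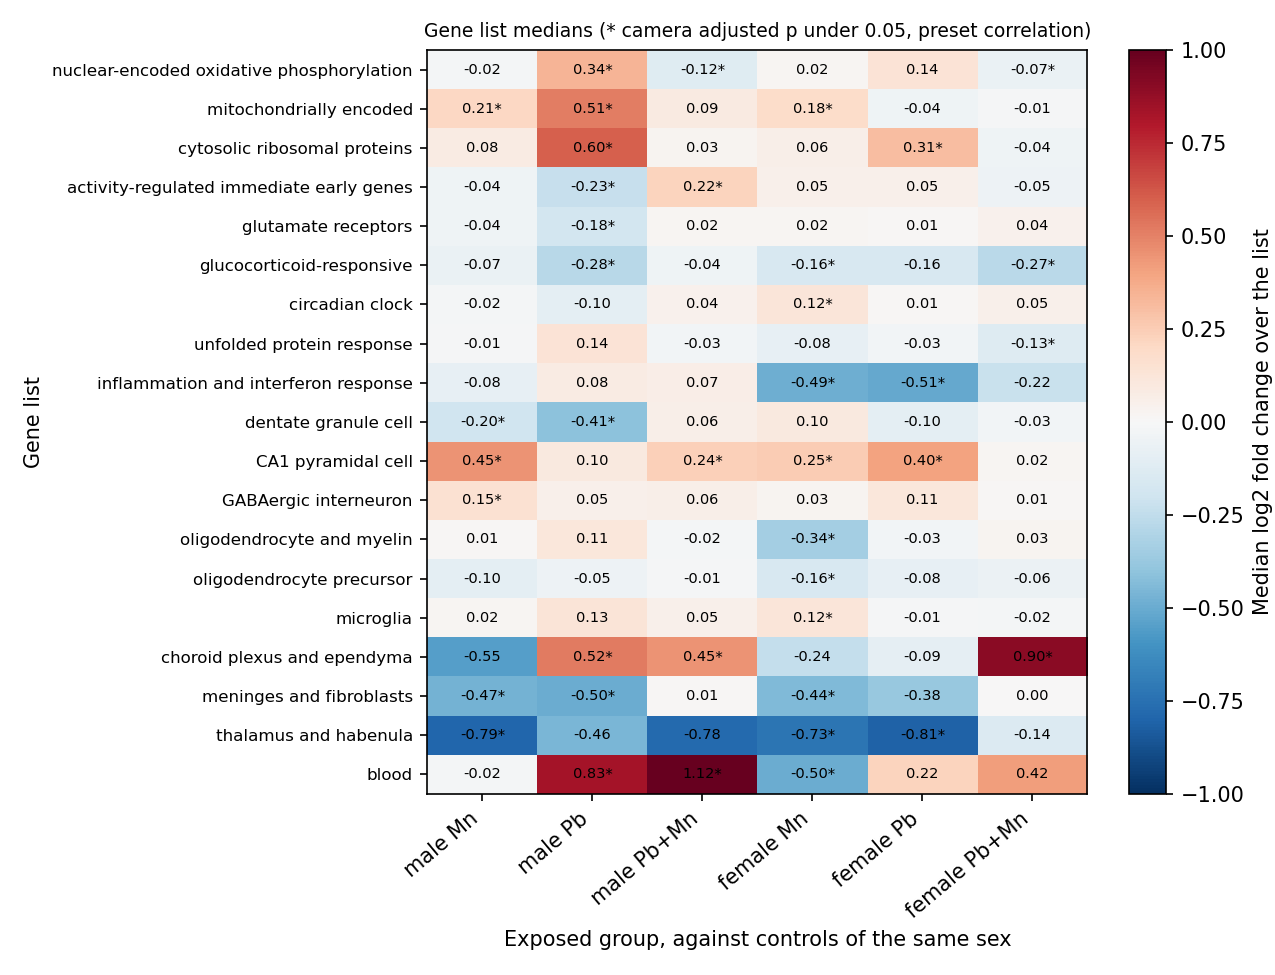
Median log2 fold change (colour and printed value) of the gene lists called in at least 1 comparison (vertical axis) in the 6 exposed groups against controls of the same sex (horizontal axis), with an asterisk at a camera adjusted p under 0.05 at the preset correlation. The myelin list stands at -0.34 in female Mn and 0.01 in male Mn, and the ribosomal list at 0.60 in male Pb.

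Whether an exposure acts differently in the sexes was tested by the sex by exposure interaction. It gave 0 genes for Mn (156 at an unadjusted p under 0.05), 0 for Pb (338) and 0 for Pb+Mn (129) in edgeR, and DESeq2 and limma voom called 0. The unadjusted count for Pb was 574 without male Pb 2, 605 without male Pb 5, 2175 without female Pb 2 and 206 without female Pb 5, and for Pb+Mn 195 without female control 5. Same-numbered males and females may share a litter, and with such pairs as a block it gave 0, 0 and 0 (224, 419 and 170 unadjusted). Among the lists, all 16 myelin genes had a higher Mn effect in males than in females (median difference 0.36, camera adjusted p = 7.2e-15), and ribosomal genes a higher Pb effect in males (30 of 30, median 0.30, adjusted p = 1.3e-07). Immediate early genes had a higher Pb+Mn effect in males (21 of 22, median 0.23, adjusted p = 1.1e-06). With an estimated correlation, the adjusted p was 0.25, 0.66 and 0.41 for these lists. Without female Mn 1 and female Mn 5 the myelin difference was 0.12 (15 of 16, adjusted p = 0.0062, 4.8e-21 to 0.93 over its alternatives). The ribosomal difference was 0.06 without male Pb 6, 0.15 without female control 1, 0.63 without female Pb 2 and 0.18 without female Pb 5, and the immediate early difference 0.15 without male Pb+Mn 1 and 0.15 without female Pb+Mn 3.

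Genes of metal handling and social neuropeptide signalling were followed in every comparison. Slc30a10, the manganese exporter, stood at 16.2 CPM in male Mn and 15.9 CPM in male controls (log2 fold change 0.04 ± 0.15) and at 16.6 against 14.2 CPM in females (0.21 ± 0.15), and no exposure passed. Slc39a14, a manganese importer, had -0.38 ± 0.11 in male Pb (32.3 against 42.3 CPM, adjusted p = 0.34, 0.037 when adjusted over the list alone) and -0.16 ± 0.11 in male Mn. In the other groups given lead, Slc39a14 had -0.08 ± 0.11 (male Pb+Mn), -0.06 ± 0.11 (female Pb) and -0.05 ± 0.11 (female Pb+Mn). Alad, the heme synthesis enzyme inhibited by lead, had 0.33 ± 0.18 in male Pb and 0.12 ± 0.18 in female Pb. The metallothionein genes Mt1 and Mt2 had 0.25 ± 0.22 and 0.03 ± 0.29 in male Pb, and -0.34 ± 0.22 and -0.34 ± 0.29 in female Pb+Mn (-0.54 and -0.65 without female Pb+Mn 3). Oxtr, the oxytocin receptor gene, had -0.18 ± 0.24 in male Mn, 0.11 ± 0.24 in male Pb, 0.19 ± 0.23 in male Pb+Mn and -0.03 ± 0.24 in female Mn. Avpr1b, a vasopressin receptor gene, stood at 0.961 against 0.818 CPM in male Mn (0.40 ± 0.45), Fos had -0.25 ± 0.29 and Bdnf -0.05 ± 0.22. None of these passed in edgeR over all genes. The lists for oxytocin, vasopressin and social behaviour, metal transporters, heme, oxidative stress, GABA signalling, monoamine and acetylcholine receptors, extracellular matrix, adult neurogenesis, CA3 and CA2 neurons, astrocytes, endothelial cells, neocortex, striatum and sex-linked genes, 14 in all, were called in no exposure comparison. Their medians ran from -0.13 to 0.13, and their smallest camera adjusted p was 0.071.

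Fold changes of different exposures were compared across the 16360 genes, which are not independent replicates. Within males, r was 0.46 for Mn and Pb, 0.49 for Mn and Pb+Mn, and 0.29 for Pb and Pb+Mn, against 0.52 in simulated unchanged groups with the same shared controls. The covariance was 0.0408 for Mn and Pb (0.0405 simulated), 0.0357 for Mn and Pb+Mn (0.041) and 0.0242 for Pb and Pb+Mn (0.0406). With controls split, the r values were 0.07, 0.03 and -0.05. Within females r was 0.49, 0.46 and 0.34 in the same order (0.51, 0.50 and 0.52 simulated), with covariances of 0.0341, 0.0302 and 0.0213 (0.0399, 0.0389 and 0.0398 simulated) and -0.24, -0.22 and -0.28 with split controls. Between the sexes, which share no libraries, r was 0.33 for Mn, 0.38 for Pb and 0.33 for Pb+Mn, with 0 in the simulation. With controls 1 to 3 for 1 sex and 4 to 6 for the other, r was 0.05, 0.10 and 0.07, and the covariance 0.0064, 0.0149 and 0.00487 against 0.0244, 0.0309 and 0.021. Over genes of log2 CPM at least 2, without split controls, r was 0.4, 0.36 and -0.05 in males and 0.54, 0.36 and 0.17 in females. Between the sexes it was then 0.49, 0.48 and 0.48. The simulation keeps genes independent within a library, so it leaves out variation that many genes share.

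Marker levels per library were compared with exact permutation tests of 6 against 6. None of the 114 tests passed adjustment (smallest adjusted p = 0.25), and 6 had an unadjusted p under 0.05. The smallest p that such a permutation test can give is 0.0022. A single fully separated list could therefore not pass adjustment over 114 tests, and the lack of calls does not exclude differences. Mitochondrially encoded genes averaged 7.4 ± 0.31 in male Pb and 6.86 ± 0.15 in male controls (difference 0.54, exact permutation p = 0.0043, adjusted p = 0.25), and blood genes 5.04 ± 0.42 in male Pb+Mn and 4.37 ± 0.2 in male controls (0.66, exact permutation p = 0.0043, adjusted p = 0.25). CA1 markers averaged 5.3 ± 0.43 in male Mn and 4.76 ± 0.36 in male controls (0.54, exact permutation p = 0.028, adjusted p = 0.53). The same list averaged 5.24 ± 0.31 in male Pb (0.48, exact permutation p = 0.022, adjusted p = 0.53), and blood genes 5.04 ± 0.6 (0.67, exact permutation p = 0.017, adjusted p = 0.53). Ribosomal genes averaged 8.22 ± 0.5 in male Pb and 7.71 ± 0.16 in male controls (0.51, exact permutation p = 0.024, adjusted p = 0.53). With the median of a list in place of its mean, none of the 114 tests passed (smallest adjusted p = 0.39) and 8 had an unadjusted p under 0.05. In male Pb these were mitochondrially encoded genes (0.45, exact permutation p = 0.017), ribosomal genes (0.52, exact permutation p = 0.028), blood (0.50, exact permutation p = 0.017) and CA3 and CA2 neurons (-0.46, exact permutation p = 0.035, 0.01 with the mean). In male Mn they were CA3 and CA2 neurons (-0.37, exact permutation p = 0.011, -0.01 with the mean), oligodendrocyte precursors (-0.19, exact permutation p = 0.017, -0.09 with the mean) and striatum (-0.41, exact permutation p = 0.035, -0.13 with the mean), and in male Pb+Mn blood (0.42, exact permutation p = 0.011). The CA1 difference was then 0.44 in male Mn and 0.05 in male Pb (exact permutation p = 0.069 and 0.83).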

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

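Tests of the unadjusted count (its splits, their length trend, the length trend and the left-out libraries), of exchanged labels, of X chromosome number, of admixed RNA, of shuffled libraries and of switch states shared between exposures were chosen after the result was seen, while the splits by threshold, X-linked dosage, shared switch states (set when a few such genes had been seen), pair-keeping shuffles, removed scores and the comparison of Pb+Mn with Pb between the sexes were set before.

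Among 502 groups of 6 libraries, 55 held a library whose gap to the nearest other, relative to the range, passed Dixon's critical value, where chance gives about 25. Female control 1 had a length trend of -0.289, a microglia score of 5.61, Eif2s3x at 44.4 CPM, Kdm5d at 0.0944, Nfil3 at 17.7, Hba-a1 at 158 and Manf at 106 CPM. Female control 5 had Irf7 at 17.4, Rtp4 at 8.06, Ifih1 at 6.57, Ifitm3 at 36.7, Tac2 at 28 and Nwd2 at 112 CPM, and a striatum score of 3. Female control 2 had Lefty1 at 0.0404 CPM. Male control 1 had Lefty1 at 0.145 and Sst at 128, male control 3 Lrrn1 at 131, and male control 4 Xist at 24.4 and Rpl38 at 182 CPM. Male control 5 had a CA1 score of 4.08, Slc12a8 at 3.1, Prkcd at 357 and Ptpn3 at 177 CPM.

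Among exposed males, Mn 1 had Alad at 39.5 CPM and Mn 2 Zfp112 at 5.46 and Xist at 0.321. Male Pb 5 had Grm2 at 76.7, and male Pb 6 had Ndufaf8 at 29, Ndufb8 at 81.8, Cox6c at 761, Rps20 at 408, Rpl38 at 412 and S100a9 at 9.16 CPM. Male Pb+Mn 1 had Alas2 at 17.8, Pb+Mn 4 Bdnf at 56 and Pb+Mn 6 Lefty1 at 10.8 CPM. Among exposed females, Mn 3 had a meninges score of 2.15, Avpr1b at 2.11 and Slc22a6 at 1.05, and Mn 5 had mt-Nd5 at 5120 CPM. Female Pb 2 had a ribosomal score of 9.11, Rps27 at 702 and Rps14 at 964, Pb 5 an interneuron score of 5.52, and Pb 6 Prkcd at 110 and Tcf7l2 at 37.6 CPM. Female Pb+Mn 1 had Tmem72 at 82.6 and Sostdc1 at 25.9, and Pb+Mn 3 had Plin4 at 15.3, Sult1a1 at 12.7, Mt1 at 321 and Mt2 at 49.5 CPM. Female Pb+Mn 6 had Cwc22 at 36.3 CPM and a CA1 score of 5.68.

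Lists whose exposure effect differed between the sexes (camera at the preset correlation, 0 with an estimated one) had these median differences, male minus female. For Mn they were 0.35 (interferon), -0.30 (dentate granule), 0.36 (myelin) and -0.12 (endothelial). For Pb they were 0.20 (respiratory chain), 0.59 (mitochondrially encoded), 0.30 (ribosomal), -0.26 (immediate early), -0.14 (glutamate receptors), 0.59 (interferon), -0.22 (dentate granule), 0.18 (astrocyte), 0.63 (choroid plexus) and 0.52 (blood). For Pb+Mn they were 0.23 (immediate early), 0.12 (glucocorticoid), 0.24 (interferon), 0.74 (blood) and -0.15 (sex-linked).

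Of these 19 calls, 6 were kept whichever 1 library was left out, and 1 of these, myelin for Mn, also kept its median within 1.5 times. Without female Mn 1 and female Mn 5 together the myelin difference was smaller, as given above. For Mn these values moved. The interferon call was lost without female control 5 (adjusted p = 0.47, median 0.03), with 4.2e-06 to 0.93 over its alternatives. The dentate granule call was lost without female Mn 1 (adjusted p = 0.072) or female Mn 5 (0.05), with 3.1e-06 to 0.93 over its alternatives. The endothelial call was lost without male control 2 (adjusted p = 0.081), male control 4 (0.4, median -0.05), male Mn 1 (0.3, median -0.06), male Mn 4 (0.12), female control 3 (0.15), female control 5 (0.065), female control 6 (0.1), female Mn 2 (0.12), female Mn 5 (0.05) or female Mn 6 (0.19), with 0.0021 to 0.93 over its alternatives. The interferon median moved to 0.60 without male control 3 with the call kept. The dentate granule median moved to -0.18 without male control 6 with the call kept. For Pb these values moved. The respiratory chain call was lost without male Pb 6 (adjusted p = 0.39, median -0.01) or female control 1 (0.21, median 0.06), with 2.5e-06 to 0.84 over its alternatives. The immediate early call was lost without male control 1 (adjusted p = 0.093), male control 2 (0.067), male control 3 (0.12), male Pb 2 (0.093), male Pb 4 (0.073), male Pb 5 (0.056), male Pb 6 (0.1), female control 2 (0.074), female control 4 (0.065), female control 5 (0.11), female Pb 2 (0.052), female Pb 3 (0.083) or female Pb 5 (0.4, median -0.15), with 0.0012 to 0.84 over its alternatives. The glutamate receptor call was lost without male Pb 6 (adjusted p = 0.1), female control 1 (0.13, median -0.09), female Pb 3 (0.053), female Pb 4 (0.059) or female Pb 5 (0.081), with 0.0011 to 0.84 over its alternatives. The dentate granule call was lost without male control 2 (adjusted p = 0.067), male control 3 (0.063), male control 6 (0.16), male Pb 3 (0.067), male Pb 4 (0.073), male Pb 6 (0.062), female control 1 (0.088), female control 4 (0.091), female Pb 1 (0.074), female Pb 3 (0.11) or female Pb 5 (0.081), with 0.0013 to 0.84 over its alternatives. The astrocyte call was lost without male Pb 1 (adjusted p = 0.08) or female Pb 2 (0.051), with 0.00039 to 0.82 over its alternatives. The blood call was lost without male Pb 5 (adjusted p = 0.095, median 0.28), male Pb 6 (0.15), female control 1 (0.22, median 0.15), female Pb 3 (0.11), female Pb 4 (0.059) or female Pb 6 (0.055), with 0.0024 to 0.84 over its alternatives. The respiratory chain median moved to 0.47 without female Pb 2, 0.12 without female Pb 3, 0.10 without female Pb 4 and 0.11 without female Pb 5 with the call kept. The mitochondrially encoded median moved to 0.34 without female control 1 with the call kept. The ribosomal median moved to 0.06 without male Pb 6, 0.15 without female control 1, 0.63 without female Pb 2 and 0.18 without female Pb 5 with the call kept. The glutamate receptor median moved to -0.23 without male control 1, -0.24 without female control 5 and -0.29 without female Pb 2 with the call kept. The interferon median moved to 0.25 without female control 5 with the call kept. The choroid plexus median moved to 0.41 without male control 1, 1.86 without male control 3, 0.32 without male control 5, 0 without male Pb 2 and 0.12 without female control 5 with the call kept. The blood median moved to 0.79 without female Pb 1 with the call kept. For Pb+Mn these values moved. The glucocorticoid call was lost without male control 6 (adjusted p = 0.054), male Pb+Mn 4 (0.078, median 0.07) or female control 3 (0.4, median 0.01), with 0.00025 to 1 over its alternatives. The interferon call was lost without male control 6 (adjusted p = 0.051) or female control 5 (1, median -0.04), with 5.9e-05 to 1 over its alternatives. The blood call was lost without male Pb+Mn 1 (adjusted p = 0.16, median 0.40), female control 1 (0.45, median 0.21), female Pb+Mn 3 (0.2) or female Pb+Mn 4 (0.15), with 0.0028 to 1 over its alternatives. The sex-linked call was lost without male Pb+Mn 2 (adjusted p = 0.059), female control 1 (0.12, median -0.06) or female Pb+Mn 3 (0.054), with 0.0063 to 1 over its alternatives. The immediate early median moved to 0.15 without male Pb+Mn 1 and 0.15 without female Pb+Mn 3 with the call kept. The glucocorticoid median moved to 0.20 without male control 1, 0.20 without female control 1 and 0.07 without female Pb+Mn 4 with the call kept. The sex-linked median moved to -0.09 without male control 4 with the call kept.

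For the 15 exposure and interaction comparisons, 100 of 100 splits of the libraries gave at least the 0 genes of the real groups. Any split gives at least 0 genes, so these counts say nothing about chance. The highest other split called 1 gene in male Mn, 398 in male Pb, 30 in male Pb+Mn, 11 in female Mn, 1126 in female Pb and 1 in female Pb+Mn. It called 1 and 1416 in male Pb+Mn against Mn and Pb, 10 and 1 in the female comparisons, 123 and 1 in the male and female interactions, and 1, 2244 and 158 in sex by Mn, Pb and Pb+Mn. For the sex difference (7 genes) 2 of 100 splits gave as many, and the highest other gave 229, so chance is unlikely but not excluded by this count. The real groups are 1 of the 100 in every count of splits or shuffles here. Splits calling many times the real count point to a structure of the samples. The first principal component (16.8% of the variance) had r = 0.81 with the length trend over 48 libraries, with male Pb 6 (trend -0.407) and female Pb 2 (-0.362) lowest on both. Over the other splits of a comparison, the number of genes at an unadjusted p under 0.05 followed the difference in trend with a Spearman r of 0.85 in male Pb+Mn against Pb, 0.81 in sex by Pb, 0.67 in female Pb, 0.62 in male Pb and 0.06 to 0.64 in the other 12.

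The first pattern is the 3895 genes at an unadjusted p under 0.05 in male Pb+Mn against Pb. Chance is not excluded, since 5 of 100 splits gave as many (highest other 5043). Without male Pb 6 the count was 1369, above the 818 expected by chance but under 2 times it, so whether that library is the whole cause stays open (2080 without it and female Pb 2). Fragmentation of RNA followed by the length trend is a candidate explanation, since the count was 1096 with the trend as covariate, but male Pb 6 also has the lowest trend of its group (-0.407). A lead effect was not tested: both groups received lead, so the r of 0.38 between the sexes (24 of 100 splits of the female libraries gave as much, highest other 0.54) measures adding manganese, and the bound set for it beforehand decides nothing about lead.

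The second pattern is sex-linked expression in 2 libraries. Female control 1 also lay apart, with 18 CPM of Xist against 29.8 to 495 CPM in the 22 females without it and female Pb 4. The cause of its low Xist was not tested. In female Pb 4, without Xist, Ddx3y was at 0 CPM, against an exchange with a male, and the median log2 ratio of 395 X-linked genes to other females was 0 (other females -0.17 to 0.08), against a pair of active X chromosomes. Eif2s3x was at 35.2 CPM, below each of the 23 other females (44.4 CPM in female control 1, 51.9 to 62.4 CPM in the other 22). It was near the males (35.4 to 42.7 CPM without male control 4). Kdm6a (21.8 CPM) and Kdm5c (67.7 CPM) lay nearer the male means (20.7 and 59.9) than the female (27.4 and 78.3). Ddx3x, at 186 CPM, lay nearer the female mean (194, against 144 in males). The mean log2 CPM of these 4 X-linked genes was 5.8, within the males (5.15 to 5.82 without male control 4) and above 2 of the 23 females. Those 2, female control 1 (5.61) and female Pb 2 (5.63), had length trends of -0.289 and -0.362, against 0.12 in female Pb 4. The rest of the 23 had 6 to 6.32. Ddx3x ranged from 81.9 to 200 CPM in males and from 87.9 to 273 CPM in females. These ranges overlap, so Ddx3x at 186 CPM does not argue against a single X chromosome. Whether only 1 is present stays open, since the 4-gene mean was above 2 of the 23 females. In male control 4, Xist was 22.8% of the median of 107 CPM in 22 females (without female control 1 and female Pb 4). Kdm6a, Kdm5c and Ddx3x (22.7, 55.4 and 135 CPM) lay nearer the male means (20.7, 59.9 and 144) than the female (27.4, 78.3 and 194). The 4-gene mean was 5.72, within the other males (5.15 to 5.82). These values argue against a second X chromosome in all cells. It is not excluded, since Eif2s3x was at 45.3 CPM, above the other males (35.4 to 42.7). Eif2s3x was also above female control 1, a weak bound since Xist was low in that library too. The 4-gene mean was also above female control 1 (5.61) and female Pb 2 (5.63). Their length trends were -0.289 and -0.362, against -0.033 in male control 4. Admixed female RNA stays open too, since the median ratio of 4 Y-linked genes to other males was 0.912 (3 of 23 other males lower, lowest 0.702), and no explanation by exposure was tested.

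The third pattern is that male and female groups of 1 exposure resembled each other, with 8 of 8 group means best matching the same exposure in the other sex and a matched minus unmatched r across 16352 genes, which are not independent replicates, of 0.42. When libraries were shuffled over exposures, no other shuffle gave as much (1 of 100, the real grouping itself, highest other 0.35), which argues against chance. Shuffles that keep same-numbered pairs together do not exclude chance (7 of 100 with the real grouping counted, highest other 0.49). Same-numbered males and females may be littermates, a test set when a few such genes had been seen: they shared 78.3% of the on or off states of 24 switch-like genes, against a median of 64.1% and a 95th percentile of 67.5% over 10000 renumberings (one-sided permutation p = 1e-04, the smallest they can give), while same-numbered males and females of different exposures, which cannot share a dam, shared 60.2% (median 61.3%, p = 0.88). After thalamus, choroid and length scores were removed, 0.25 remained, above the bound set beforehand. No shuffles were run for this remainder, so whether dissection and RNA quality are the whole cause stays open. An exposure effect common to both sexes (matched r 0.32, unmatched -0.11) cannot be told apart from dams, litters or a batch of each exposure.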

How the results depend on the processing

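The fits without libraries, with the length trend or with tissue scores, the block in the list tests, the block across the sexes and leaving out each library or one far from its group, were chosen after the data were seen. Of 276 counts of genes past the threshold under up to 18 settings, 271 were within 1.5 times the first value, and each exposure against its control stayed at 0. For male Pb+Mn against Pb, 0 in edgeR became 202 with DESeq2, 471 with limma voom with library weights, 893 at a threshold of 0.10 and 1 with thalamus and choroid scores. For the sex difference, 7 became 4 on the compared groups alone. Leaving out 1 library at a time, counts ran from 0 to 1 in male Pb and from 0 to 1483 in male Pb+Mn against Pb, and in the other 14 comparisons they stayed at 0, or at 7 for the sex difference. Of 3085 values of named genes, 3009 kept direction and side of the threshold, 7 fell below it and 69 changed sign or came to 0. Animal numbers did not pair exposed with control animals within a sex (mean r -0.015, 6 of 36 pairs over 0.1). Between exposures, same-numbered animals had a mean r of 0.16 in female Mn and Pb (4 of 6 over 0.1, adjusted p = 0.2) and 0.08 in male Mn and Pb+Mn (3 of 6, adjusted p = 0.2), and no pair of groups had every r over 0.1. With the replicate block the 15 exposure and interaction counts stayed at 0, the sex difference at 7, list calls at 6, 10, 5, 11, 4 and 4, and the correlations within a sex were 0.43, 0.48 and 0.27 in males and 0.50, 0.44 and 0.37 in females.

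The block within a sex changed no list call. Across the sexes, same-numbered animals of an exposure had a mean r of 0.172, and 15 of 24 pairs were over 0.1 (5 of 6 in Mn and in Pb+Mn, 3 in controls and 2 in Pb; adjusted p = 0.059, 0.039, 0.21 and 0.61). Male Mn and female Pb, which cannot share a dam, had as high a mean r (0.24, 5 of 6 over 0.1, adjusted p = 0.064) as Mn (0.25), so the r alone does not mark litters. With these pairs as a block the sex interactions stayed at 0 genes, the sex difference was 5, and list calls were 5, 12 and 5 for sex by Mn, Pb and Pb+Mn (4, 10 and 5 without it). List calls fell to 0 in all 9 comparisons with an estimated correlation and with fry. Without female control 5 they were 6 in female Mn and 8 in sex by Mn, without male control 4, female control 1 and female Pb 4 they were 9 in female Pb, and without female Pb+Mn 1 they were 2 in female Pb+Mn. Leaving out 1 library at a time, list calls ran from 5 to 12 in male Mn, 8 to 14 in male Pb, 4 to 7 in male Pb+Mn, 6 to 17 in female Mn, 5 to 9 in female Pb, 2 to 6 in female Pb+Mn, and 2 to 10, 6 to 14 and 3 to 8 in sex by Mn, Pb and Pb+Mn. With the length trend they were 2 in female Pb+Mn, 8 in sex by Mn and 4 in sex by Pb, and with thalamus and choroid scores 2 in female Pb+Mn and 3 in sex by Pb+Mn. With split controls, r was 0.07 (male Mn and Pb), 0.03 (male Mn and Pb+Mn), -0.05 (male Pb and Pb+Mn), -0.24, -0.22 and -0.28 (females, same order), and 0.05, 0.10 and 0.07 between the sexes for Mn, Pb and Pb+Mn. Over genes of log2 CPM at least 2, r was 0.36 (male Mn and Pb+Mn), -0.05 (male Pb and Pb+Mn), 0.36 and 0.17 (female Mn and Pb+Mn, Pb and Pb+Mn), and 0.49 and 0.48 between the sexes for Mn and Pb+Mn. For all of these the cause was not tested.

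Named genes whose log2 fold change against control changed sign, none past the threshold, were these, and the cause was not tested. Without male control 4, female control 1 and female Pb 4 values were in male Mn Xist 0.87, Alad 0.01, Mt2 0.05, in male Pb+Mn Xist 0.51, in female Mn Alad 0.07, Mt1 0.04, Mt2 0.02, Hba-a1 0.08, in female Pb Slc30a10 -0.17, Mt2 0.12, in female Pb+Mn Oxtr -0.05. With surrogate variables values were in male Mn Alad 0.05, Mt1 -0.01, in male Pb Mt1 -0.02, Mt2 -0.28, in male Pb+Mn Oxtr -0.04, Kl -0.02, in female Mn Fos 0.02, Bdnf -0.09, in female Pb Mt1 0, Fos 0.06, in female Pb+Mn Oxtr -0.12. Without male control 5 values were in male Mn Alad 0.02, in male Pb Mt2 0, Avpr1b -0.10, in female Pb+Mn Oxtr 0. With thalamus and choroid scores values were in male Mn Mt1 0, in male Pb Mt2 -0.04, Oxtr -0.01, Avpr1b -0.08, in male Pb+Mn Bdnf 0.02, in female Pb Fos 0, in female Pb+Mn Oxtr -0.02. With limma voom with library weights values were in male Mn Bdnf 0.07, in male Pb Mt2 -0.20, Oxtr -0.09, in male Pb+Mn Avpr1b 0.15, Bdnf 0.11, in female Mn Mt1 0.07, Mt2 0.12, in female Pb Slc30a10 -0.17, Slc39a14 0.02, Bdnf 0.09, in female Pb+Mn Oxtr -0.05. With limma voom values were in male Pb Mt2 -0.02, Oxtr -0.02, in male Pb+Mn Avpr1b 0.14, Bdnf 0.05, in female Pb Avpr1b -0.06. Without male Pb 6 and female Pb 2 values were in male Pb Mt2 -0.15, in female Pb Slc39a14 0.05, Mt1 -0.06, Bdnf 0.03, Rps27 -0.07. With the length trend values were in male Pb Mt2 -0.16, in male Pb+Mn Slc30a10 -0.01, in female Mn Alad 0.01, Mt2 0.01, in female Pb+Mn Oxtr -0.06. Fitted on the compared groups alone values were in male Pb+Mn Slc30a10 0. Without female control 5 values were in male Pb+Mn Slc30a10 0, in female Pb Mt1 -0.02, in female Pb+Mn Oxtr -0.08. Without female Pb+Mn 1 values were in male Pb+Mn Bdnf 0, in female Pb+Mn Oxtr -0.01, Bdnf 0. With DESeq2 values were in female Mn Oxtr 0. Without female Mn 1 and female Mn 5 values were in female Mn Fos 0.11, Bdnf -0.09. Of 52 values of named genes without a library far from its group, 46 kept direction and side of the threshold and 6 changed sign or came to 0. These were Xist in male Mn (-8.94 to 0.88) and male Pb+Mn (0.52), Lefty1 in male Pb+Mn (-0.60 to 7.69), Hba-a1 in female Mn (0.08), and Rps14 (0) and Rps27 (-0.07) in female Pb, and the cause was not tested. At the depth of 6.27 to 27.6 M counts, the simulated test called 40.3% of 1.5-fold and 73.1% of 2-fold changes in male Mn. Changes of these sizes and smaller ones therefore stay open. The simulation drew genes independently, and without any change it gave 862 genes at an unadjusted p under 0.05, against 368 in the real comparison. Its shares may thus not hold for the real data.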

Other observations

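The tests of switch-like genes against exposure were chosen after the result was seen. Some genes were on in part of the 48 libraries and off in the rest, with a gap of at least 2 on the log2 scale, and 24 such genes were found. Lefty1 was on in 0 of 12 control, 4 of 12 Mn, 7 of 12 Pb and 2 of 12 Pb+Mn animals (Fisher's exact p = 0.009, adjusted p = 0.17 over 24 genes). Fisher's test takes the animals as independent, while same-numbered males and females shared the state of Lefty1 in 19 of 24 pairs. With exposures shuffled over these pairs, the permutation p was 0.049 (adjusted p = 0.43). The protocadherin gene Pcdhgb8 was on in 4, 0, 3 and 4 of 12 animals in the same order (Fisher's exact p = 0.15, adjusted p = 0.41), and the phospholipase gene Gdpd3 in 1, 2, 2 and 2 of 12 (Fisher's exact p = 1, adjusted p = 1). The ribosomal pseudogene Rps2-ps13 was on in 28 of 48 animals and Rpsa-ps10 in 20 of 48, and reads of such copies can be shared with their parent genes. None of the 24 passed adjustment in either test.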
